A study of Arabidopsis thaliana with 12 samples.

How the data were processed

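Wild-type Arabidopsis thaliana seedlings, 14 days old and kept in liquid medium, were exposed for 90 min to 1 of 3 acyl-CoAs, which are fatty acids activated by a thioester bond to coenzyme A. C18:0 CoA carries a saturated acyl chain of 18 carbons, C18:1 CoA a chain of 18 carbons with 1 double bond, and C16:0 CoA a saturated chain of 16 carbons. Each was given at 0.1% in 0.01% Pluronic F68, a non-ionic surfactant, and the control received the surfactant alone. Each of the 4 groups had 3 replicates, each a pool of 80 plants, and the labels call them biological replicates. Poly(A) RNA was sequenced as stranded paired-end libraries on an Illumina HiSeq instrument, per the labels' protocols.

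The deposited table held read counts per gene and library, split into exon, intron and whole-gene reads, per the file headers. The reads were mapped to the TAIR10 build, per the submitters' processing notes. The aligner, its version, the annotation release and the use of strand in counting were not given in the sources used here. The authors also deposited FDR-corrected p-values and differences of weighted proportions from Baggerley's test, a test on proportions of reads, for 6 comparisons, per the file headers. RPKM and other normalized columns of the same table were not used here. Unique and total exon reads were identical in every cell (0 differed), so reads that map to several genes are not in these counts. Genes with near-identical copies, such as the small heat shock protein, light-harvesting and seed storage families, are therefore measured with less certainty, and so are overlapping and antisense genes.

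The table listed 28642 genes and 1 line that named no gene, which held no exon count and was left out. Of these genes 6448 had no exon read in any library, and 1314 had an exon length of 0. Gene symbols came from a RefSeq table of the organism, in which 28009 identifiers matched. Coordinates are those of the deposited table, on TAIR10, with starts moved to count from 1. No per-sample column belonged to another sample (0 such columns).

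Exon reads were tested with edgeR 4.0.16 in R 4.3.3. All 12 libraries entered 1 quasi-likelihood model with a mean per group, TMM scaling and the filterByExpr filter, which kept 17036 genes. Tests were two-sided and Benjamini-Hochberg adjusted over those genes, with a threshold of 0.05. The biological coefficient of variation was 0.229 and the prior degrees of freedom 10.5. Intervals of gene fold changes are 95% intervals from the fitted standard error and are approximate. Levels are CPM values on TMM-scaled library sizes, given as mean ± SD with n = 3. Apart means that all 3 libraries of one group lay on one side of all 3 of the other.

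Gene lists were written before the data were examined, as were the design, the rule for named genes and most of the other settings tried. The 21 lists covered the low-oxygen core genes, the ERF-VII factors with their degradation pathway and acyl-CoA-binding proteins, fatty acid beta-oxidation with the glyoxylate cycle, fatty acid synthesis and desaturation, cuticular wax and cutin, jasmonate, early immune response, salicylic acid, ethylene, oxidative stress with mitochondrial dysfunction, detoxification, heat shock, the unfolded protein response, abscisic acid with drought and cold, touch, carbon starvation, auxin and cytokinin. Photosynthesis and root tissue lists stood for organ makeup and a circadian clock list for the time of harvest. Lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, two-sided, adjusted over the 126 results of 21 lists and 6 comparisons. Camera with an estimated correlation and fry were run beside it. Members were also adjusted over the list alone. A list's value is the median log2 fold change of its measured members.

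Each library also received a list score, the median over members of log2 CPM (prior count 2) centred on the mean of the 12 libraries. Scores were compared by exact two-sided permutation, for which 3 libraries against 3 give 20 arrangements and no p below 0.1. The interval of a score difference is the range of all differences between single libraries of both groups, a 90% exact interval. Adjusted over the 126 score tests, the smallest p was 0.969.

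Named genes followed a rule. It took the largest 8 rises and 8 falls among genes past the test in each comparison with control and 5 of each in each pair of acyl-CoAs, which gave none because no gene passed. It always took ADH1, PDC1, SUS4, PCO1, PCO2, LBD41, HRA1, HRE1, HRE2, HB1, RAP2.12, ACBP1 and ACBP2, and up to 4 members per list with the smallest p against control. Any other gene is said to have been chosen after its values were seen.

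Depth ranged from 348140 to 6126277 exon reads, 17.6-fold. A level of 3 reads corresponded to 0.490 CPM in the deepest library and 8.62 CPM in the shallowest, a floor that covers counting error only. On simulated data drawn from the real means, depths and spread, the fit for C18:0 CoA (16781 genes) recovered 2.99% of genes changed 1.5-fold, 14.9% of those changed 2-fold and 75.8% of those changed 4-fold. For C18:1 CoA (16763 genes) the shares were 1.49%, 20.9% and 74.2%, and for C16:0 CoA (16784 genes) 1.49%, 20.9% and 74.2%. Unchanged genes called in these simulations numbered 9, 3 and 2 with C18:0, C18:1 and C16:0 CoA, the 9 beside 2, 10 and 50 recovered genes of the 3 fold sizes. A list planted at a log2 change of 0.5 came out at medians of 0.34, 0.48 and 0.55 in these simulations.

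Settings fixed before the data were examined were DESeq2 size factors, no low-count filter, DESeq2 1.42.0, only the 6 libraries compared, the replicate number as a block, the i7 index and the lane as covariates, whole-gene reads, an estimated list correlation, and each replicate left out in turn. Chosen after seeing the data were a fit without the 3 shallow libraries, limma voom with sample weights, an offset that removes each library's gene length trend, a contrast of the 3 acyl-CoAs together, and the extension of the lane, whole-gene read and 6-library settings to the low-oxygen list. Pseudocount settings for normalized values were not needed because counts were deposited. The counts of replicates within each group differed by more than sampling noise, so none was treated as a repeated library.

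Libraries differed in i7 index and lane, per the file headers. All control and C18:0 CoA libraries and C18:1 CoA replicates 1 and 2 had one i7 index, and C18:1 CoA replicate 3 and all C16:0 CoA libraries the other. The 12 libraries lay on 8 lanes, with 4 pairs on a shared lane, and a term per lane left 1 residual degree of freedom. C18:0 CoA replicates 2 and 3 and C18:1 CoA replicates 1 and 2 each lay alone on a lane. A term per lane fits them exactly and gives them no weight. With it C18:1 CoA is represented by replicate 3, paired with control replicate 1. C18:0 CoA is represented by replicate 1, paired with C16:0 CoA replicate 3.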

Results

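Transcript levels were measured by RNA-seq in whole Arabidopsis seedlings after 90 min with stearoyl-CoA (C18:0 CoA), oleoyl-CoA (C18:1 CoA) or palmitoyl-CoA (C16:0 CoA), each at 0.1%, or with the surfactant vehicle alone, with 3 replicates per group. Exon reads per library were 6126277, 4830909 and 1303225 in the control replicates 1 to 3. They were 4236345, 602649 and 2500251 with C18:0 CoA, 348140, 3110153 and 4185211 with C18:1 CoA, and 2170631, 640605 and 1753673 with C16:0 CoA. The 10 most abundant genes took 2.38% to 3.65% of the reads. C18:0 CoA replicate 2, C18:1 CoA replicate 1 and C16:0 CoA replicate 2 were the shallowest, and short genes stood higher against long genes in these 3 than in the other 9 libraries. The difference between the shortest and the longest sixth of genes was 0.40, 0.45 and 1.102 (log2) in them and between -0.46 and 0.08 in the others.

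**Figure D1:**
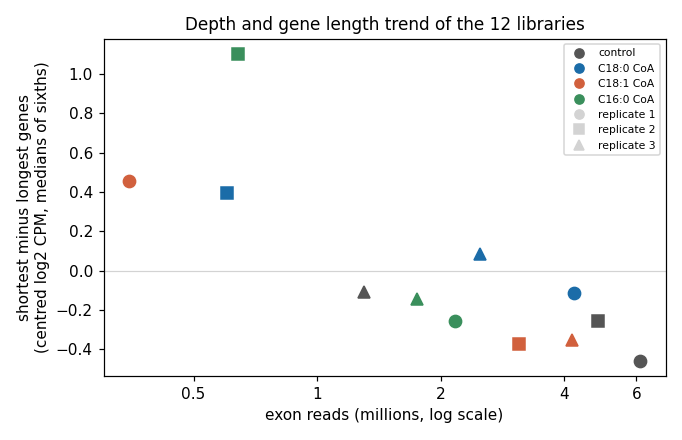
Exon reads per library (log scale) against the difference in centred log2 CPM between the shortest and the longest sixth of genes, 1 point per library, with colour for the group and shape for the replicate. C16:0 CoA replicate 2 lies highest, at 1.102, and control replicate 1, the deepest library, lowest, at -0.46.

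As far as is known of the study, it asked whether acyl-CoAs, C18:1 CoA in particular, switch on the genes that plants use when oxygen is low. Those genes are controlled by the group VII ethylene response factors (ERF-VII), among them RAP2.12, which acyl-CoA-binding proteins hold at the plasma membrane in air. The 10 low-oxygen hallmark genes named in advance had positive log2 fold changes with each of the 3 acyl-CoAs (10 of 10 each time). With C18:0, C18:1 and C16:0 CoA, 5, 3 and 8 of them had an unadjusted p under 0.05 in edgeR, and 6, 2 and 6 lay apart from the control. The 3 comparisons use the same control libraries, so they are not independent of each other. RAP2.12 itself (AT1G53910) stood at 213 ± 10.6 CPM in the control and at 232 ± 23.1, 205 ± 26.0 and 212 ± 7.56 CPM with C18:0, C18:1 and C16:0 CoA (SD, n = 3 each). Its log2 fold changes were 0.12, -0.04 and -0.01, with 95% intervals of -0.25 to 0.49, -0.41 to 0.33 and -0.38 to 0.37. The acyl-CoA-binding protein genes ACBP1 (-0.03, -0.46 and -0.10, SE 0.41 to 0.42, with 0 reads in C18:1 CoA replicate 1) and ACBP2 (0.13, 0.10 and 0.11, SE 0.37) had intervals that included 0 in all 3 comparisons. By edgeR, none of these 13 genes passed the test over all genes (0 of 17036 genes in any comparison).

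**Figure D2:**
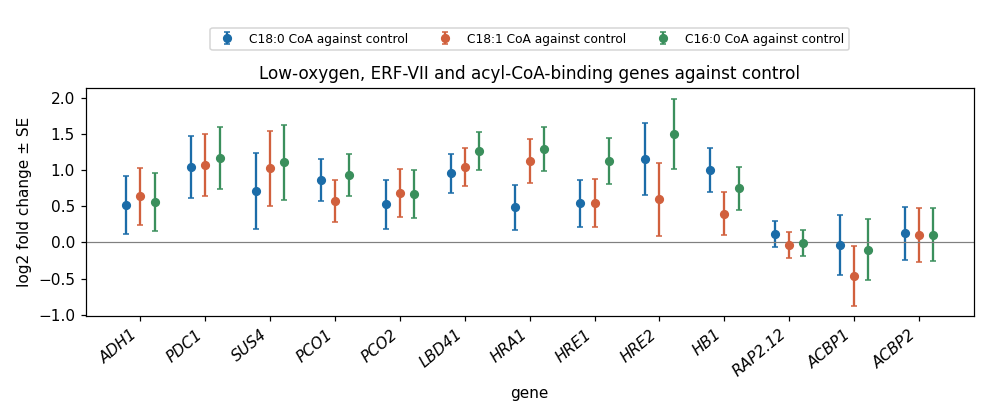
Fitted log2 fold change against control, with its SE, for the 10 low-oxygen hallmark genes, RAP2.12, ACBP1 and ACBP2, in 1 colour per acyl-CoA (n = 3 libraries per group). The 10 hallmark genes lie above 0 in all 3 colours, from 0.40 to 1.497, and the RAP2.12 values lie between -0.04 and 0.12.

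With C18:0 CoA, the saturated acyl chain of 18 carbons, the low-oxygen core genes stood higher than in the control as a group at the preset correlation (adjusted p = 0.584 with an estimated correlation). Of 53 measured members 46 had a positive log2 fold change, and the median was 0.54. PDC1, the pyruvate decarboxylase of ethanol fermentation (AT4G33070; chromosome 4, 15952289 to 15954771), was at 161 ± 21.8 CPM against 77.7 ± 20.7 (SD, n = 3), a log2 fold change of 1.04 ± 0.43 (SE). HB1, a phytoglobin that scavenges nitric oxide, was at 488 ± 188 against 244 ± 48.5 CPM, 1.00 ± 0.30. LBD41, a LOB-domain transcription factor gene, was at 131 ± 38.0 against 66.8 ± 8.40 CPM, 0.95 ± 0.26, and PCO1, an oxygen-dependent cysteine oxidase that marks ERF-VII proteins for degradation, at 99.2 ± 39.1 against 52.8 ± 7.27 CPM, 0.86 ± 0.29. ADH1, the alcohol dehydrogenase (0.52 ± 0.40), and SUS4, a sucrose synthase (0.71 ± 0.52), had intervals that included 0. PCO2 (0.53 ± 0.34), HRA1 (0.48 ± 0.31) and HRE1 (0.54 ± 0.32) were positive, also with intervals that included 0. HRE2 (1.16 ± 0.49), at only a few reads in some libraries, had an interval above 0.

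The low-oxygen list passed camera at the preset correlation with C18:0 CoA (adjusted p = 2.48e-16) and not otherwise (adjusted p = 0.584 with an estimated correlation, 0.331 between members). Unadjusted, camera with the estimated correlation gave p = 0.0362 and fry p = 0.0671, and the adjusted p of fry was 0.705. All 3 treated list scores lay above all 3 control scores, by 0.45 on average (90% exact interval 0.14 to 0.81, exact permutation p = 0.1, the smallest possible). No member passed over all genes or adjusted over the list alone (0 of 53), and 19 had an unadjusted p under 0.05, all 19 of them positive. Over all genes, edgeR called 0 rises and 0 falls, with 321 genes at an unadjusted p under 0.05 against 852 expected by chance, and DESeq2, limma voom and edgeR without the 3 shallow libraries each called 0. All 6 libraries share 1 i7 index, but no lane is shared with the control. The list median was -0.18 with a term per lane, a fit with 1 residual degree of freedom in which replicate 1 alone represents C18:0 CoA.

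No other list passed with C18:0 CoA. Heat shock, early immune and beta-oxidation genes had medians of -0.02, -0.01 and -0.01, carbon starvation, photosynthesis and touch genes of -0.01, -0.02 and 0.01, and root and cytokinin genes of -0.11 and -0.13. Adjusted over the list alone, 1 of 21 jasmonate members passed, VSP1, a vegetative storage protein gene, at 4.12 ± 1.97 against 0.446 ± 0.309 CPM. The control level is near that of 3 reads in the deepest library, so no fold is given. Cold- and drought-responsive KIN2 (1.08 ± 0.42) and the dehydrin genes ERD10 (0.50 ± 0.17) and COR47 (0.48 ± 0.20) had intervals above 0 within a list whose median was 0.06. LACS7, a peroxisomal acyl-CoA synthetase gene, was at 45.6 ± 6.24 against 67.5 ± 3.77 CPM (-0.53 ± 0.24).

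With C18:1 CoA, the monounsaturated acyl-CoA, low-oxygen genes again stood higher as a group, with 47 of 53 members positive and a median of 0.51 (adjusted p = 0.635 with an estimated correlation). HRA1, a trihelix factor that restrains RAP2.12 (AT3G10040), was at 71.1 ± 28.1 against 34.5 ± 5.16 CPM (SD, n = 3), a log2 fold change of 1.13 ± 0.31 (SE). LBD41 (1.04 ± 0.26) and the calcium-binding protein gene CML38 (1.33 ± 0.39) lay apart from the control in all 3 libraries. PDC1 (1.07 ± 0.43) had an interval above 0. SUS4 (1.02 ± 0.52), ADH1 (0.64 ± 0.40), PCO2 (0.69 ± 0.34), PCO1 (0.57 ± 0.29), HRE2 (0.60 ± 0.50), HRE1 (0.55 ± 0.33) and HB1 (0.40 ± 0.30) were positive, with intervals that included 0. At the preset correlation heat shock genes also stood higher as a group and carbon starvation, root, photosynthesis and early immune genes lower. None of these calls held otherwise (adjusted p = 0.789, 0.789, 0.584, 0.883 and 0.789 with an estimated correlation, in that order). CYP81F2, a cytochrome P450 of indole glucosinolate defence (AT5G57220; chromosome 5, 23187840 to 23189857), was at 18.8 ± 3.09 against 48.3 ± 7.02 CPM, a log2 fold change of -1.31 ± 0.25.

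The low-oxygen list passed camera at the preset correlation (adjusted p = 3.19e-14) and not otherwise (adjusted p = 0.635 with an estimated correlation). Unadjusted, camera with the estimated correlation gave p = 0.0482 and fry p = 0.104, and the adjusted p of fry was 0.794. The treated scores lay above all control scores by 0.42 on average (90% exact interval 0.03 to 0.88, exact permutation p = 0.1). No member passed over all genes, and 5 of 53 rose adjusted over the list alone, namely LBD41, HRA1, CML38, AT4G24110 and AT2G14247. The list median rested unevenly on the C18:1 CoA libraries, at 0.19 without replicate 2 and 0.78 without replicate 3, the latter being the value within the control's i7 index. It was 0.18 with a term per lane, which compares replicate 3 with control replicate 1 alone. Over all genes edgeR called 0, with 339 genes at an unadjusted p under 0.05. DESeq2 called 2, PRN higher and CYP81F2 lower, and limma voom 3, and edgeR called 5 without the 3 shallow libraries, PRN higher and PR4, GSTF2, CYP81F2 and AT3G16530 lower. PRN, PR4, GSTF2 and AT3G16530 were chosen after their values were seen. CYP81F2 also fell adjusted over its list alone, where it was the only one of 23 early immune members to pass, and its adjusted p over all genes was 0.401 in edgeR.

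Heat shock genes had a median of 0.44 with C18:1 CoA (15 of 16 positive, adjusted p = 0.00307 by camera, adjusted p = 0.789 with an estimated correlation). HSFA2, a heat shock factor gene, was at 70.4 ± 5.996 against 40.7 ± 10.3 CPM (0.80 ± 0.32). The heat shock median was 0.74 without control replicate 3, and the call ended without control replicate 1 (0.27), control replicate 2 (0.25) or C18:1 CoA replicate 3 (0.22), and with the i7 index as a covariate (0.22), while the median was 0.94 with a term per lane. Carbon starvation genes had a median of -0.43 (16 of 16 negative, adjusted p = 3.41e-05; adjusted p = 0.789 with an estimated correlation), with ASN1, the dark-induced asparagine synthetase, at -1.29 ± 0.47, and the glutamate dehydrogenase gene GDH2 at -0.58 ± 0.25. That median was -0.26 without control replicate 2, -0.19 without C18:1 CoA replicate 2, which ended the call, and 0.20 with a term per lane. Root genes had a median of -0.60 (12 of 14 negative, adjusted p = 0.000273; adjusted p = 0.584 with an estimated correlation), with the root hair expansin gene EXPA7 at -0.96 ± 0.34 and the root hair wall protein gene PRP3 at -0.59 ± 0.24. Without control replicate 2 the root median was -0.28. Score differences of heat shock, carbon starvation and root genes had 90% exact intervals that included 0. These were -0.35 to 0.95, -1.04 to 0.25 and -0.77 to 0.13 (exact permutation p = 0.3 each).

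Photosynthesis genes had a median of -0.21 with C18:1 CoA (24 of 27 negative, adjusted p = 0.0144; adjusted p = 0.883 with an estimated correlation), and the sign turned without C18:1 CoA replicate 2 (0.04). The median was -0.16 without control replicate 1 and -0.13 without control replicate 3, which ended the call, as did a term per lane (-0.06), and -0.33, -0.34 and -0.39 without control replicate 2, C18:1 CoA replicate 1 and C18:1 CoA replicate 3. Early immune genes had a median of -0.16 (16 of 23 negative, adjusted p = 0.0403; adjusted p = 0.789 with an estimated correlation). It was -0.30 without control replicate 1 and -0.29 without C18:1 CoA replicate 2, and the call ended without control replicate 2 (0.0040) or C18:1 CoA replicate 3 (-0.11) and with the i7 index (-0.10) or a term per lane (-0.09). The 5 type-A response regulator genes of the cytokinin list were all positive, with a median of 0.37 (adjusted p = 0.0283; adjusted p = 0.789 with an estimated correlation), ARR16 at 0.92 ± 0.57 and ARR6 at 0.51 ± 0.39. The call ended without control replicate 1 (0.33), control replicate 3 (0.29), C18:1 CoA replicate 1 (0.42) or C18:1 CoA replicate 2 (0.07), and with the length trend removed (0.35), limma voom (0.28) or a term per lane (-0.08). The median was 0.66 without C18:1 CoA replicate 3. Beta-oxidation and touch genes both had medians of -0.20 and did not pass, and CML38 rose adjusted over the touch list alone (1 of 11).

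With C16:0 CoA, the shorter saturated acyl-CoA, low-oxygen genes had a median of 0.66, with 43 of 53 members positive. LBD41 was at 161 ± 60.2 against 66.8 ± 8.40 CPM (SD, n = 3), a log2 fold change of 1.27 ± 0.26 (SE), and HRA1 at 81.6 ± 35.0 against 34.5 ± 5.16 CPM, 1.29 ± 0.31. The ERF-VII genes HRE1 (1.12 ± 0.32) and HRE2 (1.497 ± 0.49), PDC1 (1.17 ± 0.43), SUS4 (1.11 ± 0.52), PCO1 (0.93 ± 0.29) and HB1 (0.75 ± 0.30) had intervals above 0. PCO2 (0.67 ± 0.34) and ADH1 (0.56 ± 0.40) were positive, with intervals that included 0. At the preset correlation heat shock genes stood higher as a group, and root and beta-oxidation genes lower. None of these calls held otherwise (adjusted p = 0.584, 0.635 and 0.584 with an estimated correlation, in that order). HSFA2 was at 83.0 ± 48.6 against 40.7 ± 10.3 CPM, 1.13 ± 0.32, and the immune transcription factor gene WRKY11 at 126 ± 61.6 against 54.1 ± 4.42 CPM, 1.16 ± 0.31.

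The low-oxygen list passed camera at the preset correlation with C16:0 CoA (adjusted p = 2.48e-16) and not otherwise (adjusted p = 0.584 with an estimated correlation). Unadjusted, camera with the estimated correlation gave p = 0.0371 and fry p = 0.0506, and the adjusted p of fry was 0.672. Scores lay above all control scores by 0.51 on average (90% exact interval 0.03 to 0.96, exact permutation p = 0.1). Adjusted over the list alone, 20 of 53 members rose, among them LBD41, HRA1, HRE1, HRE2, PCO1, PDC1 and the desaturase gene SAD6, and over all genes 0 passed. Of the list of ERF-VII, degradation and acyl-CoA-binding genes, HRE1, PCO1 and HRE2 rose adjusted over the list alone (3 of 19). Over all genes edgeR called 0, with 686 genes at an unadjusted p under 0.05, against 0 called by DESeq2 and 9 by limma voom, all 9 higher and including LBD41, HRA1 and HSFA2. Without the 3 shallow libraries edgeR called 2, HRA1 (1.51, adjusted p = 0.0448) and HSFA2 (1.44, adjusted p = 0.0448), both higher. Every C16:0 CoA library has the other i7 index than the control, and with the index as a covariate, which rests on C18:1 CoA replicate 3 alone to link both, the median was 1.07. It was 0.43 without C16:0 CoA replicate 3 and 0.38 with a term per lane, and with the length trend removed the lowest treated score no longer lay above the highest control score (a gap of -0.31), while the median was 0.57.

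Heat shock genes had a median of 0.62 with C16:0 CoA (15 of 16 positive, adjusted p = 1.47e-06; adjusted p = 0.584 with an estimated correlation). HSFA2 rose adjusted over the list alone (1 of 16), and the small heat shock protein gene HSP17.8 (1.34 ± 0.50) and the coactivator gene MBF1C (1.22 ± 0.48) had intervals above 0. MBF1C was at 772 CPM in the shallow C16:0 CoA replicate 2. It was at 185 and 332 CPM in the other replicates, against up to 287 CPM in the controls. The heat shock median was 0.39 without control replicate 1, 0.31 without C16:0 CoA replicate 3, 0.34 with the i7 index as a covariate and 0.21 with a term per lane, each but the last still past the test at the preset correlation. The heat shock score difference was 0.56, with a 90% exact interval that included 0 (-0.11 to 1.29, exact permutation p = 0.3). Root genes had a median of -0.41 (11 of 14 negative, adjusted p = 0.00676; adjusted p = 0.635 with an estimated correlation), with the root hair gene COBL9 at -0.996 ± 0.50. That call ended without control replicate 2 (-0.20) or C16:0 CoA replicate 3 (-0.40) and with the i7 index (-0.37), and the median was -0.67 without C16:0 CoA replicate 1 and -0.22 without replicate 2. Beta-oxidation genes had a median of -0.20 (adjusted p = 0.0440; adjusted p = 0.584 with an estimated correlation), with the peroxisomal multifunctional protein gene MFP2 at -0.42 ± 0.22 and the acyl-CoA oxidase gene ACX1 at -0.31 ± 0.19. The call ended without control replicate 1 (-0.27), control replicate 2 (-0.12), C16:0 CoA replicate 1 (-0.31) or C16:0 CoA replicate 3 (-0.15), and was also lost with the length trend removed (-0.09), the i7 index (-0.31) or a term per lane (-0.22).

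Among early immune genes with C16:0 CoA, WRKY11 rose adjusted over the list alone (1 of 23), and WRKY22 (1.07 ± 0.36) and the ubiquitin ligase gene PUB23 (0.85 ± 0.32) had intervals above 0, while the list median was 0.16 and did not pass. Cold-responsive KIN2 (1.46 ± 0.42) and CML38 (1.34 ± 0.39) each rose adjusted over their list alone, as 1 of 12 abscisic acid, drought and cold genes and 1 of 11 touch genes. KIN2 was at 611 CPM in the shallow C16:0 CoA replicate 2. It was at 133 and 235 CPM in the other replicates, against up to 153 CPM in the controls. WRKY22 was at 266 CPM in that library and at 74.7 and 91.4 CPM in the others, against up to 77.2 CPM in the controls. Neither gene lay apart from the control. Carbon starvation and photosynthesis genes had medians of -0.22 and 0.16 and did not pass, nor did touch (0.07) and cytokinin genes (0.0072).

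**Figure D3:**
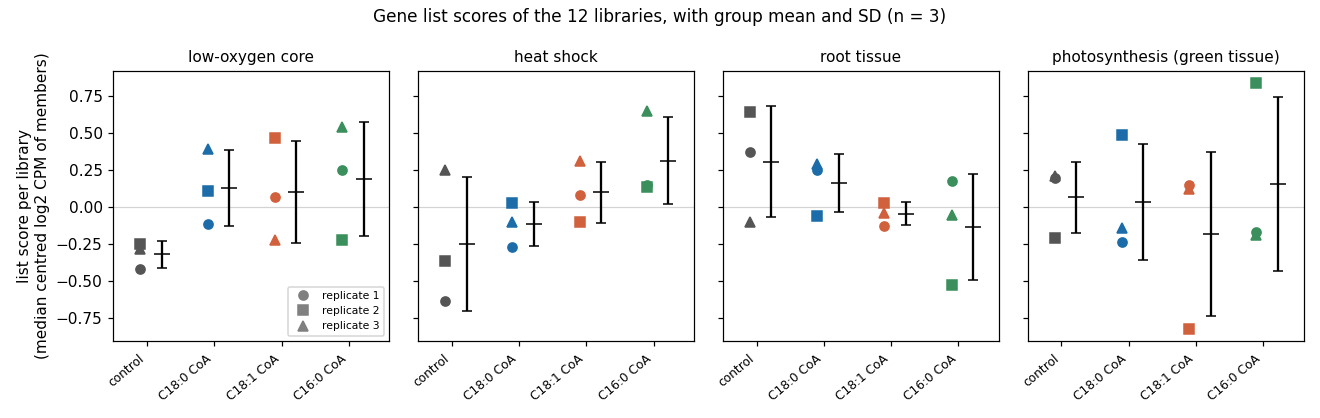
List scores of the 12 libraries (median over members of centred log2 CPM, 1 point per library, shape for the replicate) for 4 lists, with the group mean and SD (n = 3). Low-oxygen scores lie between -0.42 and -0.25 in the controls and between -0.23 and 0.54 in the treated libraries, and photosynthesis scores spread most in the treated groups.

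Of the 21 lists 12 passed in none of the 6 comparisons. Median log2 fold changes with C18:0, C18:1 and C16:0 CoA were 0.09, 0.07 and 0.11 for the ERF-VII and acyl-CoA-binding list. They were -0.08, -0.01 and -0.05 for fatty acid synthesis and -0.02, -0.02 and 0.02 for wax and cutin. Jasmonate genes had 0.01, -0.09 and -0.04, salicylic acid genes -0.08, -0.41 and 0.05, and ethylene genes -0.03, -0.10 and -0.05. Oxidative stress genes had -0.01, -0.11 and -0.21, detoxification genes -0.11, -0.26 and -0.21, and unfolded protein response genes -0.01, 0.04 and 0.02. Abscisic acid, drought and cold genes had 0.06, -0.16 and 0.0045, auxin genes -0.06, -0.11 and 0.04, and circadian clock genes -0.16, 0.07 and 0.03. Median, mean and test differed in sign in 25 of the 126 list results, of which 0 passed. The widest such gap was in salicylic acid genes with C16:0 CoA, with a median of 0.05 and a mean of -0.53.

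**Figure D4:**
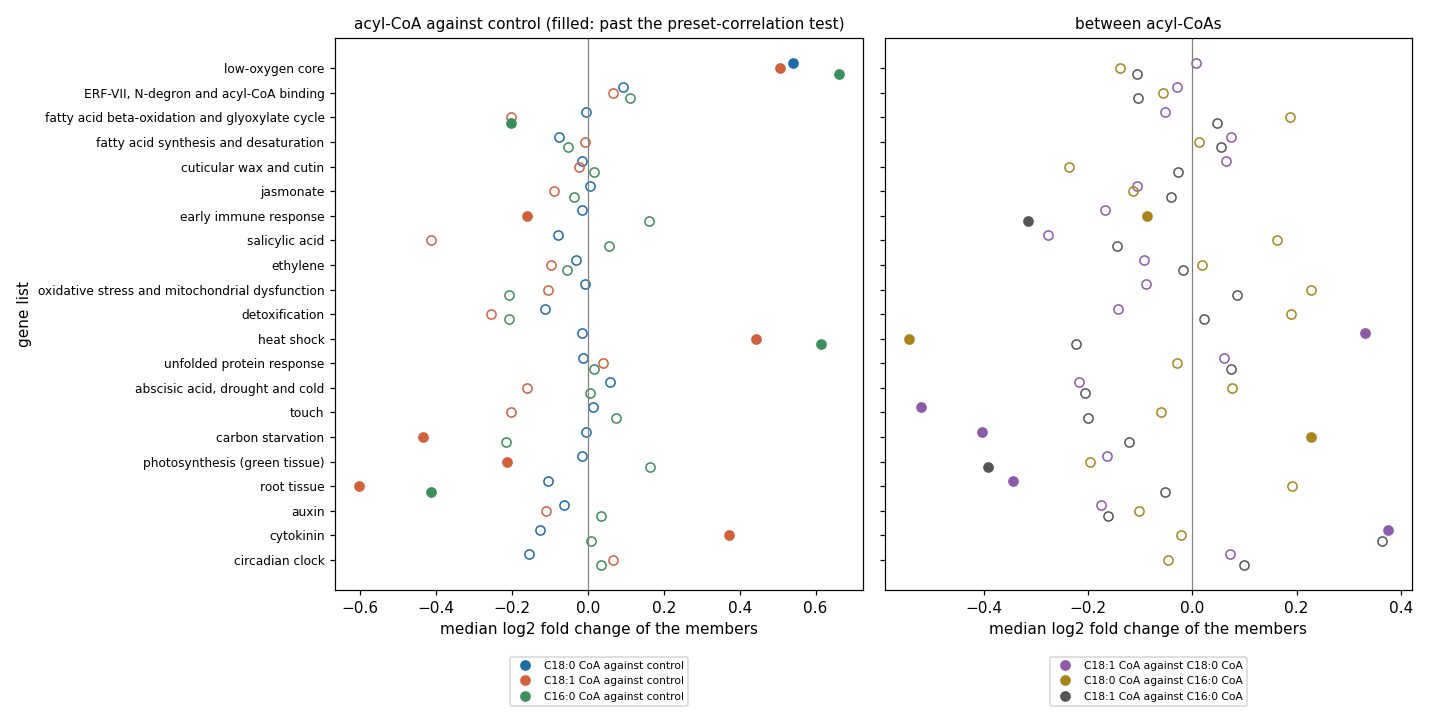
Median log2 fold change of the measured members of each of the 21 lists, against control on the left and between acyl-CoAs on the right, 1 colour per comparison, with filled points for lists past camera at the preset correlation (0 passed with an estimated correlation). The low-oxygen list lies at 0.51 to 0.66 against control and at -0.14 to 0.01 between acyl-CoAs.

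C18:1 and C18:0 CoA differ by the 1 double bond in the acyl chain. At the same concentration and time, low-oxygen genes had a median difference of 0.01 (adjusted p = 0.720) and a score difference of -0.03 (90% exact interval -0.62 to 0.58, exact permutation p = 0.9). The list passed camera as lower with C18:1 CoA without C18:1 CoA replicate 2 (-0.27, adjusted p = 0.00404). Its median was 0.38 with a term per lane, which leaves 1 library of each of these groups. Over all 12 libraries it did not pass by either form of the test (adjusted p = 0.944 with an estimated correlation). PDC1 differed by 0.04 (95% interval -0.86 to 0.93), ADH1 by 0.12 (-0.72 to 0.95) and LBD41 by 0.09 (-0.46 to 0.64). HRA1 differed by 0.64 (-0.01 to 1.29) and HB1 by -0.60 (-1.24 to 0.03). CYP81F2 was lower with C18:1 CoA, at 18.8 ± 3.09 against 42.8 ± 1.64 CPM (-1.15 ± 0.26), and fell adjusted over its list alone (1 of 23).

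Carbon starvation genes were lower with C18:1 than with C18:0 CoA as a group (median -0.40, 15 of 16 negative, adjusted p = 3.41e-05; adjusted p = 0.789 with an estimated correlation). The call ended without C18:1 CoA replicate 2 (-0.21), the median was -0.22 without C18:0 CoA replicate 2, and it was 0.33 with a term per lane. Touch genes were lower (-0.52, adjusted p = 0.0456; 0.635 as the adjusted p with an estimated correlation), root genes lower (-0.34, adjusted p = 0.0458; 0.789 likewise), heat shock genes higher (0.33, adjusted p = 0.0285; 0.849 likewise) and cytokinin genes higher (0.38, adjusted p = 0.0283; 0.789 likewise). Touch lost its call without C18:0 CoA replicate 3 (-0.46), C18:1 CoA replicate 2 (-0.44) or C18:1 CoA replicate 3 (-0.51), and with no filter (-0.41), the i7 index (-0.51), the lane term (-0.12) or the length trend removed (-0.57). Heat shock lost it without C18:0 CoA replicate 1 (0.18) or C18:1 CoA replicate 3 (0.13) and with the i7 index (0.14) or the replicate block (0.22), and stood at 1.84 with the lane term. Root lost it without C18:0 CoA replicates 1 (-0.15) or 3 (-0.28) or any of C18:1 CoA replicates 1 to 3 (-0.31, -0.49 and -0.24), and with no filter (-0.34), the replicate block (-0.27), the i7 index (-0.24) or the lane term (-0.32). Cytokinin lost it without C18:0 CoA replicate 1 (0.60) or 2 (0.20) or C18:1 CoA replicate 1 (0.31) or 2 (-0.06), without the 3 shallow libraries (0.13), and with limma voom (0.06) or the lane term (-0.04), with 0.66 without C18:1 CoA replicate 3. Over all genes 0 were called by edgeR, with 450 at an unadjusted p under 0.05, and 0 by DESeq2 and by limma voom.

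C18:0 and C16:0 CoA are both saturated and differ in chain length, 18 against 16 carbons. Low-oxygen genes had a median difference of -0.14 (adjusted p = 0.435; adjusted p = 0.944 with an estimated correlation) and a score difference of -0.06 (90% exact interval -0.65 to 0.62, exact permutation p = 0.8). The list passed camera as lower with C18:0 CoA without C18:0 CoA replicate 3 (-0.28, adjusted p = 0.00595), C16:0 CoA replicate 2 (-0.26, adjusted p = 4.48e-05) or the 3 shallow libraries (-0.34, adjusted p = 1.06e-06). It also passed with limma voom (-0.30, adjusted p = 1.69e-05) and the i7 index (-0.71, adjusted p = 1.03e-08). The median was -0.67 with a term per lane, which compares C18:0 CoA replicate 1 with C16:0 CoA replicate 3 alone. It was -0.02, -0.05 and -0.0075 without C18:0 CoA replicate 1, C16:0 CoA replicate 1 and C16:0 CoA replicate 3. None of these 3 passed, and the test pointed upward in the first and last. HRA1 differed by -0.80 (95% interval -1.45 to -0.16), and LBD41 differed by -0.31 (-0.86 to 0.24). Heat shock genes were lower with C18:0 CoA as a group (median -0.54, 15 of 16 negative, adjusted p = 7.13e-07; adjusted p = 0.584 with an estimated correlation), with a score difference of -0.43 (90% exact interval -0.92 to -0.11, exact permutation p = 0.1). HSFA2 was at 37.1 ± 6.05 against 83.0 ± 48.6 CPM (-1.21 ± 0.33) and fell adjusted over the list alone (1 of 16). The heat shock call held without any single library, and the median was -1.17 with a term per lane and -0.28 with the i7 index as a covariate, which differs between all libraries of these groups.

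Early immune genes were lower with C18:0 than with C16:0 CoA (median -0.09, adjusted p = 0.0283; adjusted p = 0.789 with an estimated correlation) and carbon starvation genes higher (0.23, adjusted p = 0.0458; adjusted p = 0.878 with an estimated correlation). The immune median turned to 0.05 without the 3 shallow libraries, and the call also ended with no filter (-0.01), limma voom (0.00083) or only the 6 libraries compared (-0.10). Its call ended without C18:0 CoA replicate 1 (-0.17) or 2 (0.02) or C16:0 CoA replicate 1 (-0.05) or 2 (5.45e-05), and the median was -0.27 without C18:0 CoA replicate 3 and -0.17 without C16:0 CoA replicate 3. The carbon starvation call ended without C18:0 CoA replicate 2 (0.04), C16:0 CoA replicate 1 (0.20) or C16:0 CoA replicate 3 (0.16), and without the 3 shallow libraries (0.07). It also ended with a term per lane (0.01), the replicate block (0.23), the length trend removed (0.20), DESeq2 size factors (0.22) or only the 6 libraries compared (0.24). Over all genes 0 were called by edgeR, with 360 at an unadjusted p under 0.05, and 0 by DESeq2 and by limma voom.

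C18:1 and C16:0 CoA differ in both chain length and the double bond. Low-oxygen genes had a median difference of -0.11 (adjusted p = 0.229; adjusted p = 0.927 with an estimated correlation) and a score difference of -0.09 (90% exact interval -0.76 to 0.69, exact permutation p = 0.7). The list passed camera as lower with C18:1 CoA without C18:1 CoA replicate 2 (-0.44, adjusted p = 0.000116), C16:0 CoA replicate 2 (-0.24, adjusted p = 3.09e-06) or the 3 shallow libraries (-0.27, adjusted p = 6.02e-07), with limma voom (-0.35, adjusted p = 5.39e-10) and with the i7 index (-0.51, adjusted p = 7.31e-09). The median was 0.09 without C18:1 CoA replicate 3 and 0.11 without C16:0 CoA replicate 3, and neither passed. ADH1 differed by 0.08 (95% interval -0.76 to 0.91) and PDC1 by -0.10 (-0.99 to 0.80). Early immune genes were lower with C18:1 CoA (median -0.32, 19 of 23 negative, adjusted p = 9.63e-05; adjusted p = 0.584 with an estimated correlation), with CYP81F2 at -1.10 ± 0.26, which fell adjusted over the list alone (1 of 23), PUB23 at -1.03 ± 0.34 and WRKY11 at -0.97 ± 0.32. The score difference was -0.48 (90% exact interval -0.79 to -0.20, exact permutation p = 0.1), and the median was -0.11 without C16:0 CoA replicate 1, still past the test. Photosynthesis genes were lower with C18:1 CoA (median -0.39, 24 of 27 negative, adjusted p = 0.000624; adjusted p = 0.872 with an estimated correlation), a value that was -0.11 without C18:1 CoA replicate 2, 0.04 without C16:0 CoA replicate 2, -0.07 without the 3 shallow libraries, -0.12 with limma voom and -0.09 with the i7 index, each of which ended the call. Over all genes edgeR called 0, with 483 at an unadjusted p under 0.05, limma voom 2 and DESeq2 1, AT5G48430, chosen after its values were seen and lower with C18:1 CoA. Without the 3 shallow libraries edgeR called 1, PRN, which was higher with C18:1 CoA.

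The 3 responses were compared with each other over 17036 genes, which are not independent replicates. Pearson's r of the log2 fold changes was 0.352 for C18:0 with C18:1 CoA, 0.489 for C18:0 with C16:0 CoA and 0.413 for C18:1 with C16:0 CoA. Simulated groups with no effect, with shared controls that were redrawn as well, gave means of 0.450, 0.438 and 0.435 (50 draws each). Genes were drawn independently and with the same spread in every library. In the real data low-oxygen genes varied together (estimated correlation 0.331 with C18:0 CoA), and sample weights in limma voom ran from 0.29 to 1.97. A position outside a simulated range therefore cannot decide whether responses are alike. Over all 12 libraries the observed r lay below the simulated range for C18:0 with C18:1 CoA (0.425 to 0.470) and for C18:1 with C16:0 CoA (0.423 to 0.450), and above it for C18:0 with C16:0 CoA (0.422 to 0.455). These positions depended on the libraries and settings, for which no simulated ranges were drawn. For C18:0 with C18:1 CoA r was -0.0595 with a term per lane, 0.194 without C18:0 CoA replicate 1, and 0.497 and 0.471 without control replicates 1 and 2. For C18:0 with C16:0 CoA it was 0.326 to 0.405 without any 1 of the 6 treated libraries, lowest without C16:0 CoA replicate 2, 0.344 without the 3 shallow libraries, 0.421 with the length trend removed, 0.383 with no filter and 0.384 with the i7 index. For C18:1 with C16:0 CoA it was 0.544, 0.475 and 0.452 without control replicates 1 to 3, 0.466 without C16:0 CoA replicate 2, 0.459 without the 3 shallow libraries, 0.741 with the i7 index and 0.0480 with a term per lane. The covariance was 0.0427, 0.0694 and 0.0589 against simulated means of 0.0683, 0.0681 and 0.0682. The differences were -0.0255, 0.00130 and -0.00922, of which those for C18:0 with C18:1 CoA and C18:1 with C16:0 CoA lay below the simulated range (lowest covariances 0.0630 and 0.0653) and that for C18:0 with C16:0 CoA within it (0.0642 to 0.0720). Without control replicate 1 the covariances were 0.0920, 0.112 and 0.120, without control replicate 2 0.0769, 0.107 and 0.0875, and with the i7 index 0.0533, 0.0968 and 0.264. With a term per lane they were -0.0194, 0.295 and 0.0115. Genes had the same sign in 62.9%, 68.5% and 63.3% of cases against a simulated 65.2%, 64.9% and 64.7%, and 0 called genes were shared because 0 were called. With 3 controls, no split leaves 2 libraries on each side, so what the shared controls add cannot be measured directly.

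In the authors' deposited table, Baggerley's test called far more genes. At an FDR-corrected p under 0.05, the authors' deposited table listed 764 genes higher and 281 lower with C18:0 CoA, 556 and 366 with C18:1 CoA, and 616 and 215 with C16:0 CoA. Of the 56 low-oxygen genes, the authors' deposited table had 20 higher and 0 lower, 13 higher and 1 lower, and 11 higher and 0 lower. Between compounds, the authors' deposited table listed 272 higher and 664 lower for C18:1 against C18:0 CoA, 165 and 183 for C16:0 against C18:0 CoA, and 426 and 195 for C16:0 against C18:1 CoA. Of the genes called in the authors' deposited table, 36.4%, 32.1% and 39.4% had treated libraries apart from all controls in the comparisons with C18:0, C18:1 and C16:0 CoA. Libraries in random order give 10%, but these genes were selected on the same libraries, so that share is no baseline for them. Of all genes tested here 12.3%, 9.28% and 11.4% lay apart in these comparisons, and of the 53 low-oxygen genes 20, 10 and 21 lay apart upward and 1, 1 and 0 downward.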

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

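Intron reads entered none of the comparisons, and their share was looked at without a test. Intron reads made up 2.69% of the reads in C18:1 CoA replicate 2 and 2.65% in C16:0 CoA replicate 1, above the highest control library (2.29%). In the other 7 treated libraries the share lay between 1.76% and 2.21%. No explanation of this difference was tested.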

How the results depend on the processing

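Chosen only after the results were seen were the fits without the 3 shallow libraries, with the length trend removed and with limma voom, and the lane, whole-gene read and 6-library settings for gene lists. Of 102 alternative counts of genes, 87 stayed at 0, including every one that left out 1 library of the groups compared (0 to 0) and those with DESeq2 size factors, the i7 index, whole-gene reads or the replicate block. With C18:0 CoA the lane term gave 1 gene. With C18:1 CoA the count was 1 with no low-count filter, 1 with only the 6 libraries compared, 1 with the length trend removed, 2 with DESeq2, 3 with limma voom and 5 without the shallow libraries. With C16:0 CoA it was 2 with the lane term, 2 without the shallow libraries and 9 with limma voom. Between C18:1 and C16:0 CoA it was 1 with no filter, 1 with the lane term, 1 without the shallow libraries, 1 with DESeq2 and 2 with limma voom. The cause of these differences was not tested, and no setting gave a gene in the 2 other pairs.

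Against control, the low-oxygen list kept its direction and its side of the threshold in 47 of 51 settings. The exceptions were the estimated correlation, which leaves the medians at 0.54, 0.51 and 0.66 but ends the call because members vary together, and the lane term with C18:0 CoA (-0.18). All settings but the estimated correlation used the preset one. At the preset correlation camera also gave an unadjusted p under 0.01 in 5, 6 and 3 of 9 other splits of the libraries with C18:0, C18:1 and C16:0 CoA. Most libraries of a group stay together in each of those splits, which keeps part of any real difference. They therefore cannot show how often the test passes by chance. Staying past that test is weak support all the same, since the calls ended with an estimated correlation. Leaving out 1 library gave medians from 0.40 to 0.66 with C18:0 CoA, 0.19 to 0.78 with C18:1 CoA and 0.43 to 0.76 with C16:0 CoA. Between acyl-CoAs, where settings were chosen after the results were seen, the list passed in 13 of 51. Leaving out 1 library gave -0.27 to 0.19 for C18:1 against C18:0 CoA, -0.28 to -0.0075 for C18:0 against C16:0 CoA and -0.44 to 0.11 for C18:1 against C16:0 CoA. In that order, the medians were 0.17, -0.71 and -0.51 with the i7 index and 0.069, -0.34 and -0.27 without the shallow libraries. The lane term gave 0.38 and -0.67 in the first 2 pairs, the length trend removed 0.094 in the first, and limma voom -0.30 and -0.35 in the last 2. Of 323 settings for the 19 other list results past the test, 222 left the call, 94 ended it and 7 turned the direction of the test. The lane term turned carbon starvation (0.20) and cytokinin (-0.079) with C18:1 CoA, and the same lists between C18:1 and C18:0 CoA (0.33 and -0.044). It leaves only C18:1 CoA replicate 3 and C18:0 CoA replicate 1 of these groups, so these turns do not describe all libraries. Leaving out the shallow libraries turned early immune genes between C18:0 and C16:0 CoA (0.046). Leaving out 1 library turned photosynthesis genes with C18:1 CoA (from -0.39 without C18:1 CoA replicate 3 to 0.043 without replicate 2) and between C18:1 and C16:0 CoA (from -0.57 without C16:0 CoA replicate 3 to 0.043 without replicate 2). The median had another sign in 12 settings, these 7 and 5 more that ended the call. Those 5 were early immune genes with C18:1 CoA without control replicate 2 (0.0040), cytokinin genes between C18:1 and C18:0 CoA without C18:1 CoA replicate 2 (-0.057), and early immune genes between C18:0 and C16:0 CoA without C18:0 CoA replicate 2 (0.016), without C16:0 CoA replicate 2 (5.45e-05) and with limma voom (0.00083). The cause was not tested.

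The correlation of C18:0 with C18:1 CoA was -0.0595 with the lane term and 0.194 to 0.497 with 1 library left out. That of C18:0 with C16:0 CoA was 0.383 with no filter, 0.384 with the i7 index, 0.687 with the lane term, 0.344 without the shallow libraries and 0.326 to 0.557 with 1 library left out. That of C18:1 with C16:0 CoA was 0.741 with the i7 index, 0.0480 with the lane term and 0.309 to 0.544 with 1 library left out. Among 2001 settings of 118 values of named genes, 8 passed the test (CYP81F2 with C18:1 CoA in 3; HRA1 and HSFA2 in 2 each and LBD41 in 1 with C16:0 CoA) and 50 had another sign. The 10 hallmark genes had another sign in 11 of 510 settings, 10 of them with the lane term.

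Replicate numbers showed no clear pairing of the libraries, but a pairing is not excluded. The correlation of same-numbered libraries after removing group means had a median of -0.0421 (-0.226 to 0.234), 5 of 18 pairs exceeded 0.1, and 5 of 12 libraries correlated best with one of their own number. The shallow C18:1 CoA replicate 1 had 0.124 and 0.206 with the other shallow libraries and -0.174 to -0.131 with its own number. Deviations that shallow libraries share could hide a pairing. With the replicate number as a block, edgeR called 0 genes in all 6 comparisons and the low-oxygen medians were 0.55, 0.49 and 0.64. The block ended 3 list calls, heat shock (0.22, adjusted p = 0.0582) and root (-0.27, adjusted p = 0.101) between C18:1 and C18:0 CoA, and carbon starvation between C18:0 and C16:0 CoA (0.23, adjusted p = 0.0540). In the shallowest library 3 reads correspond to 8.62 CPM, so lower levels were not resolved there. The median SE of a log2 fold change was 0.32 to 0.34, and what depth and replicate spread each add to it was not separated.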

Other observations

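Chosen only after the result was seen were the tests of depth, of the i7 index with C18:0 CoA, of the shallow libraries, of root tissue and of the lane, and the gaps between list scores, as well as the limma voom and length-trend fits and the joint contrast of the 3 acyl-CoAs. PRN, a pirin gene (AT3G59220; chromosome 3, 21894134 to 21895623) chosen after its values were seen, was at 266, 103 and 116 CPM in the C18:1 CoA libraries against 35.5, 38.5 and 45.6 CPM in the controls. Its log2 fold change was 1.93 ± 0.32 (SE, n = 3 per group), with an adjusted p of 0.182 in edgeR. It passed with DESeq2 (adjusted p = 0.000291), limma voom (0.00144), no filter (0.00514), the length trend removed (0.0155) and only the 6 libraries compared (0.0422). It also passed without C16:0 CoA replicate 2 (adjusted p = 0.00979), a library outside the comparison that enters the shared estimate of spread. With C18:0 CoA it stood at 47.1, 68.4 and 59.0 CPM and with C16:0 CoA at 44.1, 79.9 and 39.5 CPM. AT5G48430, also chosen after its values were seen, was at 60.3, 44.4 and 68.8 CPM with C16:0 CoA and at 8.85, 15.1 and 12.4 CPM with C18:1 CoA, a difference of -2.16 ± 0.38 (adjusted p = 0.283 in edgeR, 0.00420 in DESeq2, 0.0482 in edgeR without C18:0 CoA replicate 3). C18:1 CoA replicate 1, the shallowest library, held 3 reads of it.

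The seed storage protein genes CRA1 and CRU3, chosen after their values were seen, had 66 and 55 reads in C18:0 CoA replicate 3. In the other C18:0 CoA libraries they had 5 and 7 (CRA1) and 15 and 6 (CRU3) reads, and in the controls 3, 1 and 1 (CRA1) and 1, 6 and 6 (CRU3). Scaled for depth, CRA1 was at 1.15, 12.3 and 26.65 CPM in C18:0 CoA replicates 1 to 3, against up to 0.772 CPM in the controls. CRU3 was at 3.45, 10.5 and 22.2 CPM, against up to 4.635 CPM. The values of the shallow replicate 2 rest on the few reads given. Both belong to a family with similar copies, so their counts are uncertain. ICL, the isocitrate lyase of the glyoxylate cycle in germinating seeds, had 69 reads in C18:0 CoA replicate 3, 27.9 CPM. It had 17 and 5 reads in the other C18:0 CoA libraries (3.91 and 8.77 CPM). The controls held 15, 30 and 2 reads (2.38, 6.08 and 1.545 CPM). Its log2 fold change with C18:0 CoA was 1.92 ± 0.71 (SE) and 0.55 without C18:0 CoA replicate 3. A joint contrast of the 3 acyl-CoAs, run in edgeR alone, gave 0 genes against the control (424 at an unadjusted p under 0.05), and 0 without the shallow libraries (1059 at an unadjusted p under 0.05). The smallest p was that of LBD41 over all 12 libraries (1.09 ± 0.23, adjusted p = 1.00) and that of HRA1 without the shallow ones (1.11 ± 0.18, adjusted p = 0.149). The low-oxygen scores of 9 of 9 treated libraries lay above all 3 controls, by 0.46 on average (exact permutation p = 0.0273 over 220 arrangements, adjusted p = 0.532 over the lists). Detoxification scores lay below all 3 controls in 6 of 6 treated libraries when the shallow ones were left out (-0.33, exact permutation p = 0.0119, adjusted p = 0.25), and in 6 of 9 over all 12 libraries (-0.21, exact permutation p = 0.177, adjusted p = 0.532).

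Low-oxygen genes stood higher with each acyl-CoA as a group (adjusted p = 0.584, 0.635 and 0.584 with an estimated correlation), and an effect of the acyl-CoAs is a hypothesis beside several technical ones. Against the i7 index as the whole cause speak medians of 0.54 with C18:0 CoA, where all 6 libraries share 1 index, and 0.78 with C18:1 CoA within the control's index, where treated scores lay above all control scores by at least 0.14 and 0.32. Against the shallow libraries as the whole cause with C18:0 and C16:0 CoA speak medians of 0.53 and 0.78 without them, with scores above all controls by at least 0.16 and 0.58. With C18:1 CoA that cause stays open, since the median was 0.45 but the lower of 2 treated scores lay only 0.0021 above the highest control score. Against gene length as the whole cause with C18:0 CoA speaks a median of 0.46 with the length trend removed, with scores above all controls by at least 0.05. With C18:1 CoA gene length stays open, since the median was 0.46 but the lowest treated score lay only 0.01 above the highest control score. With C16:0 CoA gene length stays open, since the median was then 0.57, past the bound set earlier, but within the spread, as the gap from the highest control score to the lowest treated score was -0.31, and so does more root in the pools with each acyl-CoA, since root medians were -0.11 with C18:0 CoA and at most -0.41 with the others but the 90% exact intervals of the root score differences included 0 (-0.70 to 0.39, -0.77 to 0.13 and -1.17 to 0.28). Also open is the lane with C18:0 CoA (-0.18 with a lane term, in a comparison with 0 shared lanes). The lane is open with C18:1 CoA too, as the lane term (0.18) compares replicate 3 with control replicate 1 alone. Its replicates 1 and 2, on which the 0.78 rests, share no lane with a control. Open as well is the i7 index with C16:0 CoA, whose median of 1.07 with that covariate rests on the 1 library that links both indices. That makes the bound set for it earlier unusable.

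The 6 libraries of a comparison can be split in 10 ways, too few for a share under 0.05. In 10 of 10 splits at least as many genes were called as in the real one. That outcome was fixed, because the real count was 0 in each of the 6 comparisons, so it says nothing about chance. The highest count in another split was 3 with C18:0 CoA, 0 with C18:1 CoA and 0 with C16:0 CoA against control. Between acyl-CoAs it was 0 for C18:1 against C18:0 CoA, 1 for C18:0 against C16:0 CoA and 2 for C18:1 against C16:0 CoA. The low-oxygen median was as far from 0 as in the real split in 1 of 10 splits for each acyl-CoA, the real one itself, with real values of 0.54, 0.51 and 0.66 and highest other values of 0.41, 0.46 and 0.47. Camera at the preset correlation gave an unadjusted p under 0.01 in 5, 6 and 3 of the 9 other splits. Most libraries of a group stay together in these splits, which keeps part of any real difference. These counts therefore do not measure how often that test passes by chance.

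The 3 shallow libraries, C18:0 CoA replicate 2, C18:1 CoA replicate 1 and C16:0 CoA replicate 2, correlated less with the deep libraries (0.891, 0.843 and 0.828 across genes, which are not independent) than control replicate 1 did when thinned to the same depths (lowest values 0.947, 0.916 and 0.949). Depth alone is therefore an unlikely cause, as the smallest gap was 0.0563. Only control replicate 1 was thinned, however, so how much other deep libraries would differ at those depths was not measured. Removing the length trend left a gap of at least 0.0506, which speaks against gene length as the whole cause. RNA quality was not analysed here and stays open, and no biological explanation was tested.

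The authors' deposited table calls 1045, 922 and 831 genes with C18:0, C18:1 and C16:0 CoA where edgeR calls 0, and the candidate explanations are that its calls include genes whose replicates overlap and genes set apart by length. Both had the values set for them before the result was seen. At most 39.4% of the called genes had treated libraries apart from all controls. That exceeds the share among all tested genes (at most 12.3%), but the called genes were selected for a difference in these same libraries. Such a selection raises the share even among false calls. These shares therefore do not show whether the calls are true or false. A count of 0 in edgeR does not show it either, since edgeR recovered 14.9% to 20.9% of genes changed 2-fold in simulations. The median exon length of called genes was as low as 62.2% of that of all tested genes. Genes higher in the authors' deposited table had median exon lengths of 881, 1036 and 874 bases with C18:0, C18:1 and C16:0 CoA, and genes lower had 1678, 1365 and 1545, against 1591 for all tested genes.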
